A study of Mus musculus with 6 samples.

How the data were processed

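The data were 6 Affymetrix arrays of macrophages from digested skin of wild-type mouse embryos, 3 of LYVE-1 positive and 3 of LYVE-1 negative cells. Per the labels' protocols, cells were selected with magnetic beads for F4/80 and then separated by LYVE-1, and labelled cDNA was made from total RNA by a whole-transcript sense-strand protocol. The deposited table holds log2 expression values per probe set, which the authors made with RMA and Partek 6.3, per the submitters' processing notes. RMA corrects background, normalizes between arrays at the probe level and summarises probes. Whether other arrays were normalized together with these, and the genome build, are not given in the sources used here, so no coordinates are printed. The table had no detection flags, so that a dim gene cannot be told from one not above background, and a fold change of a dim gene is compressed.

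The table holds 35399 probe sets. The platform annotation lists a gene for 23410 of them, with a single symbol for 21789 and several for 1621, and lists none for 11989. Gene identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, which held those of 21698 single-symbol probe sets and not those of 91, with 0 differing symbols. Probe sets with several or no symbols were left out of the comparison by gene. Where a gene had more than 1 probe set, as 999 genes did, the one with the highest mean over all arrays was used, which left 19938 genes. No dim genes were filtered out.

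The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, group as the only factor, all 6 arrays). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Errors are SD over arrays for group means and SE for differences. The arrays give no counts, and their number limits the precision. Gene lists of 18 pathways and 16 cell types were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 34 lists, with an estimated correlation and fry beside it. Camera compares a list with all other genes, while fry tests whether its genes move one way and compares them with no other genes. Each list's median change was also placed among 10000 random lists of the same size, each member drawn from the 50 genes on either side in mean expression. List members without a single-symbol probe set were not analysed here.

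The design, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took Lyve1 and Adgre1, the 12 largest changes in each direction among called genes whose groups did not overlap (without predicted, Riken, small nucleolar and microRNA genes), up to 4 members with the smallest p from each list, and Vegfa, Vegfc, Vegfd, Tnf, Mmp9, Wnt7b, Prox1 and Csf1r. Not all members that the rule allows are named. Cpa3, Hdc, Cma1, Gata2, Tpsb2, Kit, Col1a1, Col1a2 and Col6a1 were chosen after their values were seen. Of the named genes with several single-symbol probe sets, Trio and Mitf had probe sets that disagreed in size or direction, and those of Dnajc13 ranged from 0.98 to 4.67 in their log2 change.

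Alternatives were the replicate number as a block, median centring, quantile normalization, a filter on dim genes, the average of a gene's probe sets, other eBayes options, array weights, leaving out arrays, all probe sets, an unmoderated test per gene and other thresholds. Cyclic loess normalization, which removes each array's trend with brightness, and a fit without the LYVE-1 negative arrays 2 and 3 were added after the data were examined, because those arrays had the narrowest range of values. The second leaves 1 negative array, which is assumed to vary like the positive ones.

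The scripts were tested on simulated data for the same comparison over 19938 genes. Of 100 genes changed by 1.5 log2 units 54 were recovered, and of 100 changed by 3 log2 units 93, with 7 unchanged genes among 154 calls. A planted list was called with the preset correlation and had an adjusted p of 0.0858 with an estimated correlation (camera), with 0 other lists called. The simulated noise was independent between genes, with the same SD in both groups, and held no trend with brightness. The few false calls and the 0 other lists called therefore do not carry over to the real arrays, whose range of signal differed between the groups. Figures were drawn with matplotlib 3.10.9.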

Results

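Gene expression was measured in macrophages of wild-type mouse embryonic skin at embryonic day 15.5. Cells of the digested skin were enriched with magnetic beads for F4/80, a surface protein of mouse macrophages encoded by Adgre1. The enriched cells were then split with beads for LYVE-1, the hyaluronan receptor encoded by Lyve1, which is carried by lymphatic endothelium and by a subset of tissue macrophages. The comparison asks how the expression profile of LYVE-1 positive macrophages differs from that of the LYVE-1 negative cells of the same enrichment. There were 6 Affymetrix arrays, 3 of LYVE-1 positive and 3 of LYVE-1 negative macrophages, and 19938 genes were tested. The labels do not say whether replicates came from separate litters, so that p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision of every value.

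Lyve1 (probe set 10566934) was higher on all 3 LYVE-1 positive arrays, at 9.74, 9.92 and 10.71 log2 units, against 7.79, 5.21 and 5.52 on the LYVE-1 negative arrays 1, 2 and 3. The difference was 3.95 ± 0.59 log2 units (SE, n = 3 and 3), a 15.4-fold change with an adjusted p of 0.00128 in limma. As the gene of the sort marker, Lyve1 checks the labels and is no finding of its own. Adgre1 (10446282), on which both groups had been enriched, was also higher in the positive samples, at 8.15 ± 0.70 against 4.80 ± 0.77 (SD, n = 3 each). Its difference was 3.35 ± 0.44 (SE), with an adjusted p of 0.000975. Csf1r (10456071), the receptor for the macrophage growth factor CSF1, stood at 10.47 ± 0.38 against 6.16 ± 2.13 and differed by 4.30 ± 0.83 (SE), with an adjusted p of 0.00291. Among the 1000 genes nearest in brightness on the positive arrays, Lyve1 lay above 95.8% of changes, Adgre1 above 88.5% and Csf1r above 98.8%. Only 169 genes had a mean above 9 there, so that most neighbours of Lyve1 and Csf1r were dimmer than they were. These neighbours had a median change of 2.77, against 3.31 in the 169 genes. Since changes rose with brightness, the percentiles of such bright genes come out high by themselves. With the brightness trend of each array removed, Lyve1 stood at 0.41 (adjusted p = 0.301) and Csf1r at 0.68 (0.0674), neither past the threshold, while Adgre1 passed at 0.90 (0.0288). Without the LYVE-1 negative arrays 2 and 3 Lyve1 was higher by 2.33, and under quantile normalization by 2.04 (adjusted p = 0.0322).

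**Figure D1:**
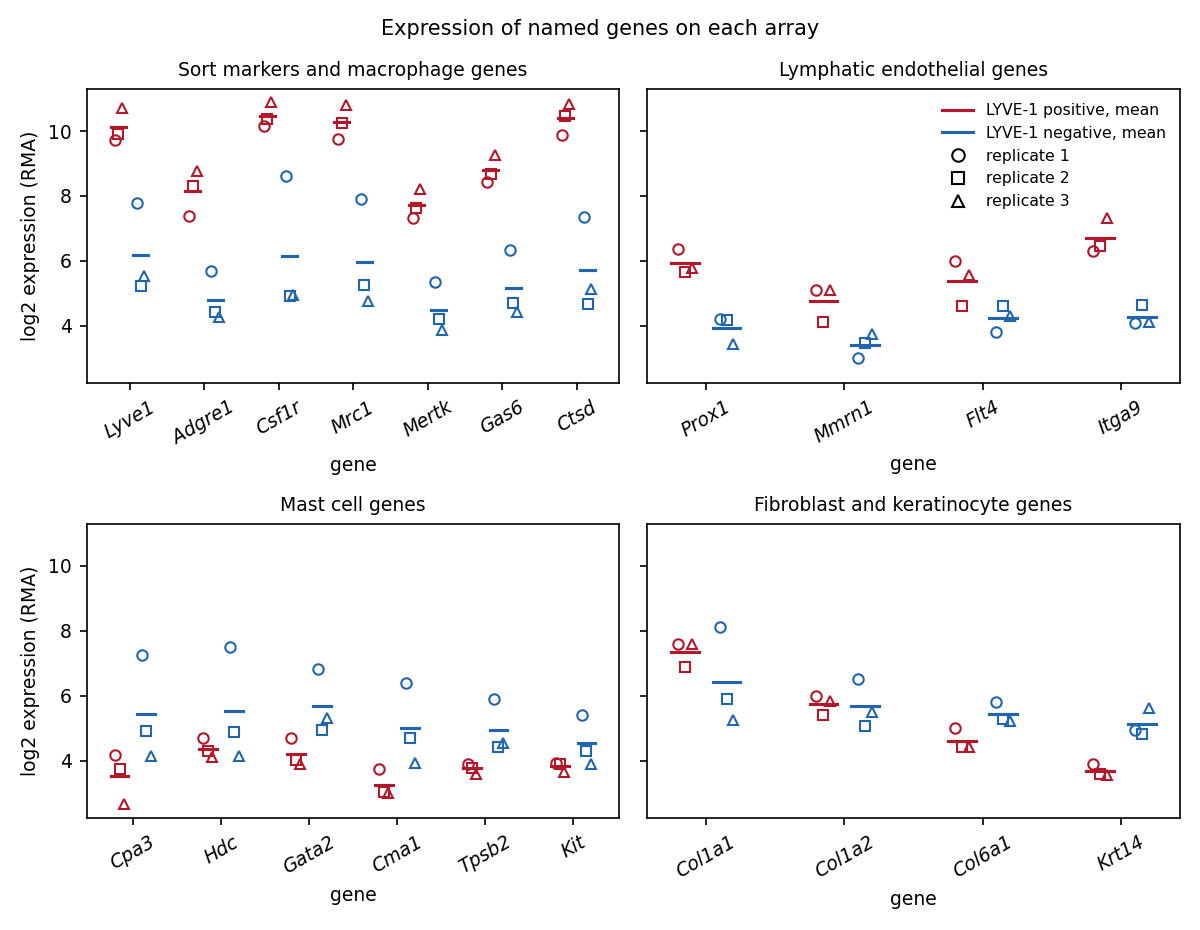
Expression of single genes on each array, in log2 units (RMA), by gene; red marks are LYVE-1 positive and blue marks LYVE-1 negative samples, symbols are replicates and short lines are group means (n = 3). Lyve1 lies between 9.74 and 10.71 on the positive arrays and between 5.21 and 7.79 on the negative arrays, while the mast cell gene Cpa3 reaches 7.24 on LYVE-1 negative array 1 alone.

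The arrays of the groups differed in the range of their signal. The SD over genes was 1.49, 1.55 and 1.73 log2 units on the positive arrays 1, 2 and 3, and 1.01, 0.68 and 0.68 on the negative arrays 1, 2 and 3. Between 396 and 677 genes reached 8 log2 units on a positive array, against 164, 24 and 13 on the negative arrays. Ribosomal protein genes, which every cell uses, lay 6.0 to 6.8 log2 units above olfactory receptor genes on the positive arrays, and 5.66, 2.42 and 1.28 above them on the negative arrays. Across genes, which are not independent replicates, positive arrays correlated with each other at 0.958 to 0.979 and negative arrays at 0.546 to 0.686. The negative array 1 correlated at 0.864, 0.825 and 0.775 with the positive arrays 1, 2 and 3, and at 0.661 and 0.546 with the negative arrays 2 and 3. Dim genes were mostly lower and bright genes mostly higher in the positive samples. Among the 1621 genes with a mean of up to 3 log2 units over all 6 arrays the median change was -0.927 and 85.6% were called lower, while among the 218 genes between 7 and 8 it was 2.84 and 88.5% were called higher. Grouping by a mean that shares arrays with the difference can by itself bring such a trend. Grouped by the negative arrays alone, which by itself would bring the opposite one, the medians were -0.701 in the 236 dimmest genes, 1.99 in the 55 genes between 7 and 8 and -0.001 in the 12 above 9. The 1027 olfactory receptor genes had a median change of -0.998, with 883 called lower and 0 higher. The 55 ribosomal protein genes had a median of 1.99, with 31 called higher and 2 lower, which turned to -1.14 once the brightness trend of each array was removed.

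**Figure D2:**
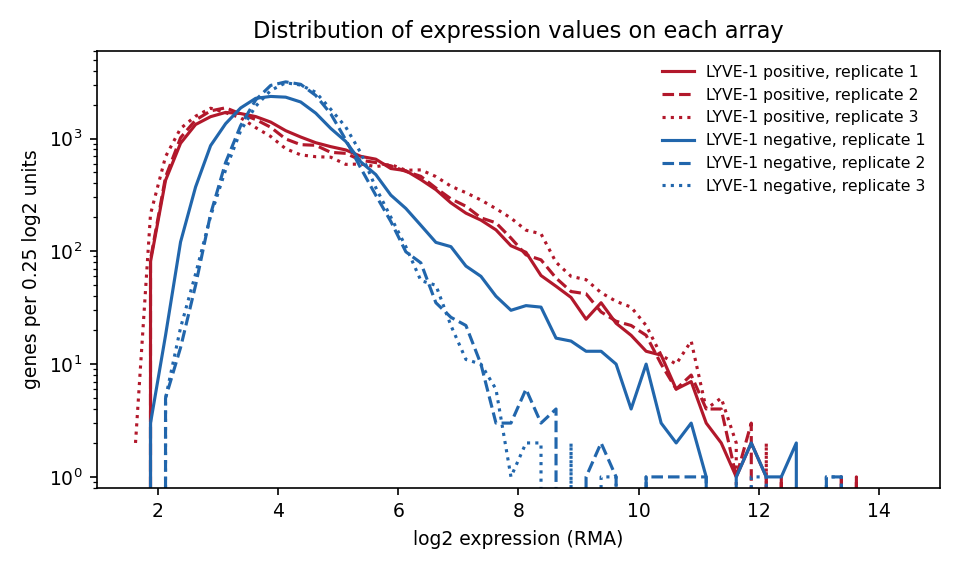
Number of genes (log axis) per 0.25 log2 units of expression on each array; red lines are LYVE-1 positive and blue lines LYVE-1 negative samples. The LYVE-1 negative arrays 2 and 3 have the narrowest distributions, with 24 and 13 genes at 8 log2 units or more.

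**Figure D3:**
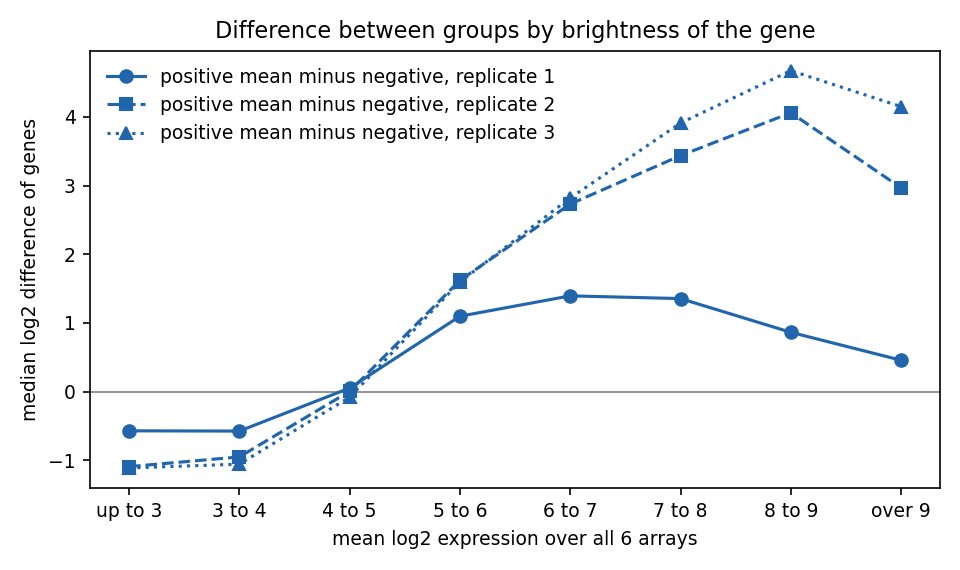
Median log2 difference between the mean of the 3 LYVE-1 positive arrays and each LYVE-1 negative array, for genes binned by their mean log2 expression over all 6 arrays. Between 7 and 8 log2 units the median difference is 1.35, 3.44 and 3.91 for the negative arrays 1, 2 and 3, and in the dimmest bin it is -0.57, -1.09 and -1.11.

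Over all genes, 5286 were higher and 8757 lower in LYVE-1 positive than in LYVE-1 negative macrophages at an adjusted p under 0.05 (limma), 70.4% of those tested. At least a 2-fold change was seen for 4322 and 4542 of them. The groups did not overlap for 76.3% of genes, where chance gives 10%. The median gene changed by -0.51, so that shifts of gene lists are given relative to it, and values of single genes as measured. The balance of the calls depended on the scale and on the arrays used. Centring each array on its median gave 6338 higher and 3972 lower, and quantile normalization gave 1809 and 1244. Removal of the brightness trend by cyclic loess, an alternative chosen after the data were examined, gave 2579 and 2474. Of the genes called on the deposited scale, 3376 were also called in the same direction with the trend removed, and 209 in the opposite direction. Without the LYVE-1 negative arrays 2 and 3, also chosen afterwards, 3209 genes were higher and 3809 lower. Leaving out replicate 2 of both groups gave 2489 higher and 739 lower, leaving out replicate 3 gave 3311 and 2435, and leaving out replicate 1 gave 5315 and 9197. Without the positive array 2 or 3 alone, 5691 and 5803 genes were lower.

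Among genes whose groups did not overlap, the 12 largest increases included lysosomal, endocytic and actin-binding genes, with no test of such groups among the 12. Ctsd, the lysosomal protease cathepsin D, was 25.6-fold higher, at 10.39 ± 0.49 against 5.71 ± 1.43 (SD, n = 3 each). F13a1, coagulation factor XIII A chain, was 24.4-fold higher, Slc40a1, the iron exporter ferroportin, 21.2-fold, and Ctsc, cathepsin C, 20.8-fold. Mrc1, the mannose receptor, and Grn, the progranulin precursor, were each 19.8-fold higher. Slc9a9, an endosomal sodium-proton exchanger, was higher by 4.63 ± 0.42 log2 units (SE). The other members of the 12 were Hnrnpk, an RNA-binding protein, at 4.87, Cltc, the clathrin heavy chain, at 4.81, Dnajc13 at 4.67, Cap1 at 4.59 and Capza1, which caps actin filaments, at 4.50. Their adjusted p-values lay between 0.000839 and 0.00489 (limma). Without the LYVE-1 negative arrays 2 and 3, which leaves 1 negative array, all 12 were still higher on the deposited scale, but by less. F13a1 then stood at 2.26 log2 units instead of 4.61, Ctsc at 2.13 instead of 4.38 and Grn at 1.81 instead of 4.31. Slc40a1 stood at 2.81, and the 12 ranged from 1.498 for Dnajc13 to 3.76 for Slc9a9. With the brightness trend removed, Slc9a9 was still 2.05 higher, Capza1 2.00, Slc40a1 1.93, Cap1 1.82, Hnrnpk 1.76, Cltc 1.54, Ctsc 1.26, Ctsd 1.20, F13a1 0.94 and Mrc1 0.79, while Dnajc13 and Grn, at 1.32 and 0.47, no longer passed.

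Of the genes with the 12 largest decreases, all but Trio had means of 2.08 to 4.39 log2 units in the positive samples. In the negative samples the means of these 11 lay between 4.37 and 6.47. The median over all probe sets was 3.92 to 4.17 on the negative arrays. On negative array 1, with a median of 3.92, Svs3b (3.40), Serpina1c (3.50) and Klk1b24 (3.63) lay below it and the others above it. Trio, a guanine nucleotide exchange factor, changed by -4.01 ± 0.48 (SE), from 9.75 ± 0.34 in the negative to 5.74 ± 1.10 in the positive samples (SD, n = 3 each). Its probe sets disagreed in size, since the other one, 10427928, changed by -0.33 where 10427991 changed by -4.01. Apol7d changed by -2.68, Svs3b, a seminal vesicle protein, by -2.37, Serpina1c, an alpha-1-antitrypsin, by -2.29 and Try5, a trypsin, by -2.28. Pramel27 changed by -2.16, Nanog, a transcription factor of pluripotent cells, and Krt33b, a hair keratin, both by -2.08, and Prm1, the sperm protamine, Klk1b24 and Mpped2 each by -2.06. Olfr1392, an olfactory receptor, changed by -2.05. All 12 also passed, in the same direction, with the trend removed. That step enlarged the changes of Trio to -7.30, Krt33b to -3.53, Prm1 to -3.03 and Nanog to -2.30. The others became smaller, from -2.26 for Apol7d to -1.18 for Klk1b24. The same step turned the median of ribosomal protein genes to -1.14, so that passing it does not settle these decreases.

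Genes of macrophage identity and of endocytosis were called higher in LYVE-1 positive samples as groups with the preset correlation, and not with an estimated one. All 16 core macrophage genes were higher, among them Mertk, a receptor for apoptotic cells, by 3.25 and Ptprc, the pan-leukocyte antigen CD45, by 2.66. The list shifted by 3.29 relative to the median gene (camera, adjusted p = 1.36e-07; adjusted p = 0.332 with an estimated correlation). Of 24 genes of LYVE-1-high resident macrophages, 19 were higher and 1 lower, with Gas6, a ligand of MERTK, at 3.64, Mgl2, a C-type lectin, at 2.11 and Folr2, a folate receptor, at 2.39 (list shift 2.66, adjusted p = 6.67e-06, and adjusted p = 0.332 with an estimated correlation). In the lysosome list 19 of 21 genes were higher and 1 lower, with Lamp2 at 3.32 and Ctsl at 3.33. It shifted by 3.86, with an adjusted p of 1.93e-08, and an adjusted p of 0.332 with an estimated correlation. Among 23 scavenger and endocytic receptors 15 were higher and 3 lower, including Fcgr4, an Fc receptor, at 2.13 and Scarb1, a lipoprotein receptor, at 2.58 (shift 2.39, adjusted p = 0.000195, and adjusted p = 0.332 with an estimated correlation). Brightness alone went with shifts of this kind. The median changes of these lists were 2.78, 2.15, 3.35 and 1.88 in the order given, against 2.24, 1.63, 2.56 and 0.85 in 10000 lists of equally bright genes, which placed them at percentiles 97.94, 93.57, 99.97 and 99.91. With the trend removed, the lysosome and scavenger lists were still called higher (camera, adjusted p = 0.0139 and 0.0167; adjusted p = 0.735 and 0.660 with an estimated correlation), and the core macrophage and resident lists were not (both 0.162). The members called higher then numbered 4 of 16 core macrophage genes, with 2 lower, 8 of 24 resident genes, with 2 lower, 9 of 21 lysosome genes and 6 of 23 scavenger genes, with 0 lower in both. The genes named here had the smallest p-values of their lists, and Folr2 and Scarb1 among them lost their calls.

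Further groups of genes used in immune signalling, clearance and growth were called higher by camera with the preset correlation, and not with an estimated one. Fry, which compares a list with no other genes, also called each of them higher. Of 21 inflammatory cytokine and chemokine genes 16 were higher and 2 lower, with Cxcl10 at 3.61, Ccl7 at 3.40 and Tnfaip3, an inhibitor of NF-kappa B signalling, at 3.46 (list shift 3.26, adjusted p = 3.28e-05, adjusted p = 0.332 with an estimated correlation). Of 25 cell cycle genes 23 were higher and 0 lower, including Ccna2, cyclin A2, at 2.72 and Mcm6, a subunit of the replicative helicase, at 2.91 (2.40, adjusted p = 1.06e-09, adjusted p = 0.332 with an estimated correlation). All 19 measured immediate early and dissociation stress genes were higher, such as Jun at 3.34 and Fosb at 3.32 (3.02, adjusted p = 2.82e-08, adjusted p = 0.332 with an estimated correlation), but the camera direction of this list was lower once the trend was removed. Iron and haem genes were higher for 13 of 18, with Ncoa4, a ferritin receptor, at 2.70 (2.28, adjusted p = 0.00012, adjusted p = 0.332 with an estimated correlation), and lipid handling and efferocytosis genes for 11 of 19, with Abca1, a cholesterol exporter, at 3.49 and Lipa, the lysosomal acid lipase, at 3.08 (1.64, adjusted p = 0.000748, adjusted p = 0.332 with an estimated correlation). Of 14 complement genes 7 were higher and 2 lower, with C1qc at 3.27 and Cfp, properdin, at 2.15 (1.84, adjusted p = 0.0354, adjusted p = 0.339 with an estimated correlation). With the trend removed C1qc stood at -0.45 and Cfp at -0.0238, neither past the threshold. The microglia-like signature had 9 of 15 genes higher and 1 lower (1.57, camera, adjusted p = 0.00764, adjusted p = 0.332 with an estimated correlation). In it Cx3cr1, the fractalkine receptor, was at 3.74, P2ry13 at 2.28 and the lower gene, Sall1, at -1.10. Glycolysis and hypoxia genes were higher for 13 of 18, with the glucose transporter Slc2a1 at 1.80 and Pfkfb3 at 2.30 (2.32, adjusted p = 0.000136, adjusted p = 0.332 with an estimated correlation), and this list turned lower with the trend removed and the negative arrays 2 and 3 left out. In the order given, the list medians were 2.75, 1.89, 2.51, 1.77, 1.13, 1.33, 1.06 and 1.81, against 1.98, 1.46, 2.60, 1.33, 1.01, 0.68, 0.79 and 1.41 in equally bright lists. With the trend removed, Ccl7, Ccna2, Ncoa4, Abca1 and Lipa still passed, and Cxcl10, Tnfaip3, Mcm6, Jun, Fosb, Cx3cr1, P2ry13, Sall1, Slc2a1 and Pfkfb3 did not. The members then called higher numbered 2 inflammatory (1 lower), 7 cell cycle, 0 immediate early (5 lower), 6 iron (2 lower), 4 lipid (1 lower), 1 complement (1 lower), 3 microglia-like and 2 glycolysis genes (2 lower). Of these 8 lists only the cell cycle list was then called (camera, adjusted p = 0.0167, and adjusted p = 0.660 with an estimated correlation).

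Genes that act on vessels did not move as one group. Of 23 angiogenic and lymphangiogenic factors 3 were higher and 12 lower, and the list shift of -0.16 was not called (adjusted p = 0.24). Vegfa, the main growth factor of blood vessels, changed by -0.68 ± 0.23 (SE; adjusted p = 0.023), from 4.56 ± 0.16 to 3.87 ± 0.13 (SD, n = 3 each). The lymphatic growth factors Vegfc and Vegfd changed by -0.72 ± 0.25 (adjusted p = 0.0294) and -0.59 ± 0.24 (0.0445). Relative to the median gene the 3 changes were -0.18, -0.21 and -0.08, and all lost the call with the trend removed, where Vegfa stood at -0.36 (adjusted p = 0.18), Vegfc at 0.05 and Vegfd at 0.16. Vegfb was higher by 1.88 and Sema3c, a semaphorin, lower at -1.39, and neither passed with the trend removed. Tnf was higher by 2.67 ± 0.65 (adjusted p = 0.00679), Mmp9, a matrix protease, changed by -1.05 ± 0.26 (0.00696) and Wnt7b, a Wnt ligand that macrophages can give to vessels, by -1.11 ± 0.28 (0.00829). Relative to the median gene Mmp9 and Wnt7b stood at -0.54 and -0.60. None of these passed with the trend removed, where Tnf stood at -0.63 (adjusted p = 0.125), Mmp9 at -0.38 (0.163) and Wnt7b at -0.55 (0.095). Tnf lay above 44.0% of the 1000 genes nearest to it in brightness on the positive arrays, and above 55.5% of those nearest over all 6 arrays. Markers of proangiogenic macrophages were called higher as a list (9 of 16 higher and 5 lower, shift 1.91, adjusted p = 0.0385, and adjusted p = 0.332 with an estimated correlation). Its median change was 1.40, against 0.88 in equally bright lists (percentile 91.33). The list lost its call with the trend removed (shift 0.17, adjusted p = 0.677, 3 members higher), under quantile normalization (0.129) and without the negative arrays 2 and 3 (0.07). In it the neuropilins Nrp1 and Nrp2, co-receptors for VEGF and semaphorins, were higher by 3.25 and 2.46, and with the trend removed by 1.27 and 1.26, both past the threshold. Matrix remodelling enzymes went both ways, with 7 of 21 higher and 9 lower (0.59, adjusted p = 0.414), including Adam17, the TNF-releasing protease, higher by 2.50, a call that held with the trend removed.

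Alternative activation genes had 4 of 16 higher, such as Il4ra, the interleukin 4 receptor, by 3.37, and 6 lower, such as Socs2 at -1.18, with an uncalled shift of -0.01 (adjusted p = 0.964). The list median of -0.52 lay below 0 while camera gave the direction as higher. Of 12 genes of MHC class II antigen presentation 3 were higher and 6 lower, with the costimulatory gene Cd86 higher by 3.50 and H2-Ob at -1.03 (-0.11, adjusted p = 0.985). Interferon response genes were higher for 6 and lower for 5 of 17 (0.63, adjusted p = 0.336), with Stat2 higher by 1.29. Of the genes named for these lists only Cd86 passed with the trend removed. Camera gave the first 2 of these lists opposite directions under different scalings.

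Genes of other skin cell types were mostly dim in both groups. In the lymphatic endothelial list 4 of 16 genes were higher and 1 lower, and the shift of 0.64 was not called (adjusted p = 0.133). Prox1, the transcription factor that sets lymphatic identity, was higher by 2.00 ± 0.30 (SE; adjusted p = 0.00133), at 5.93 ± 0.38 against 3.93 ± 0.44 (SD, n = 3 each). With the trend removed it was higher by 1.21 (adjusted p = 0.0181). Itga9 was higher by 2.41, Mmrn1 by 1.35 and Flt4, the receptor for VEGF-C, by 1.13. Of these only Mmrn1 still passed with the trend removed, at 1.84, where 2 members of the list were higher and 3 lower. Keratinocyte genes were lower for 14 of 20 and higher for 0, with Krt14 at -1.43 and Epcam at -1.20 (shift -0.52, adjusted p = 0.00573, and adjusted p = 0.332 with an estimated correlation). Neutrophil genes were lower for 15 of 17, with the protease gene Ctsg at -1.50 and S100a9, a calprotectin subunit, at -1.20 (-0.54, adjusted p = 0.0051, and adjusted p = 0.514 with an estimated correlation). Lymphocyte genes were lower for 15 of 17, with Il7r at -1.43 and Cd79a at -1.82 (-0.45, adjusted p = 0.0297, and adjusted p = 0.518 with an estimated correlation). Dim genes as a class were lower in the positive samples, and equally bright lists had medians of -0.70, -0.85 and -0.82 against -1.03, -1.05 and -0.95 for these 3, which placed them at percentiles 1.12, 3.08 and 13.22. With the trend removed none of the 3 lists was called (camera, adjusted p = 0.162, 0.162 and 0.26), and 3, 2 and 2 of their members were lower. Krt14 and Ctsg were still called lower, and Epcam, S100a9, Il7r and Cd79a were not.

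Dermal fibroblast and mesenchymal genes were lower for 12 of 24 and higher for 0 (shift -0.10, adjusted p = 0.0843). They were called lower as a list with the trend removed (shift -0.45, camera, adjusted p = 0.0139, and adjusted p = 0.735 with an estimated correlation), with Fbln2 at -1.10. Mast cell genes were lower for 12 of 17 (-0.49, adjusted p = 0.0507), with Mcpt4 at -1.05, while Hpgds, the haematopoietic prostaglandin D synthase, was higher by 3.04. The other cell type lists were not called. Blood vessel endothelium shifted by 0.30 (adjusted p = 0.501), with Pecam1 higher by 0.98 and Kdr by 0.92, and turned lower with the trend removed. Mural cells shifted by -0.14 (0.0676), skeletal muscle by -0.34 (0.0785) with Des at -1.43 and Myod1 at -1.41, and Schwann cells and melanocytes by -0.38 (0.133) with Ngfr at -1.23. In the last list Mitf was 1.16 higher by its probe set 10540248, while 10540265 changed by -0.90. Eosinophils and basophils shifted by -0.39 (0.0593) with Epx at -1.15, monocytes by -0.17 (0.811) with Itga4 at 2.24 and Spn at -1.42, and dendritic cells by -0.23 (0.225) with Cd83 at 2.68 and Flt3 at -1.22. The dendritic cell list took opposite directions under different scalings. Langerhans cells shifted by -0.40 (0.561) with Runx3 at -1.19, and erythroid cells by -0.23 (0.222) with the erythropoietin receptor Epor at 2.25 and Klf1 at -1.62. Megakaryocytes and platelets lay at the median gene (0.441), with Vwf at -1.09. Among the genes named for cell types from mast cells onward, Mcpt4, Epx, Itga4, Cd83 and Flt3 lost their calls with the trend removed.

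**Figure D4:**
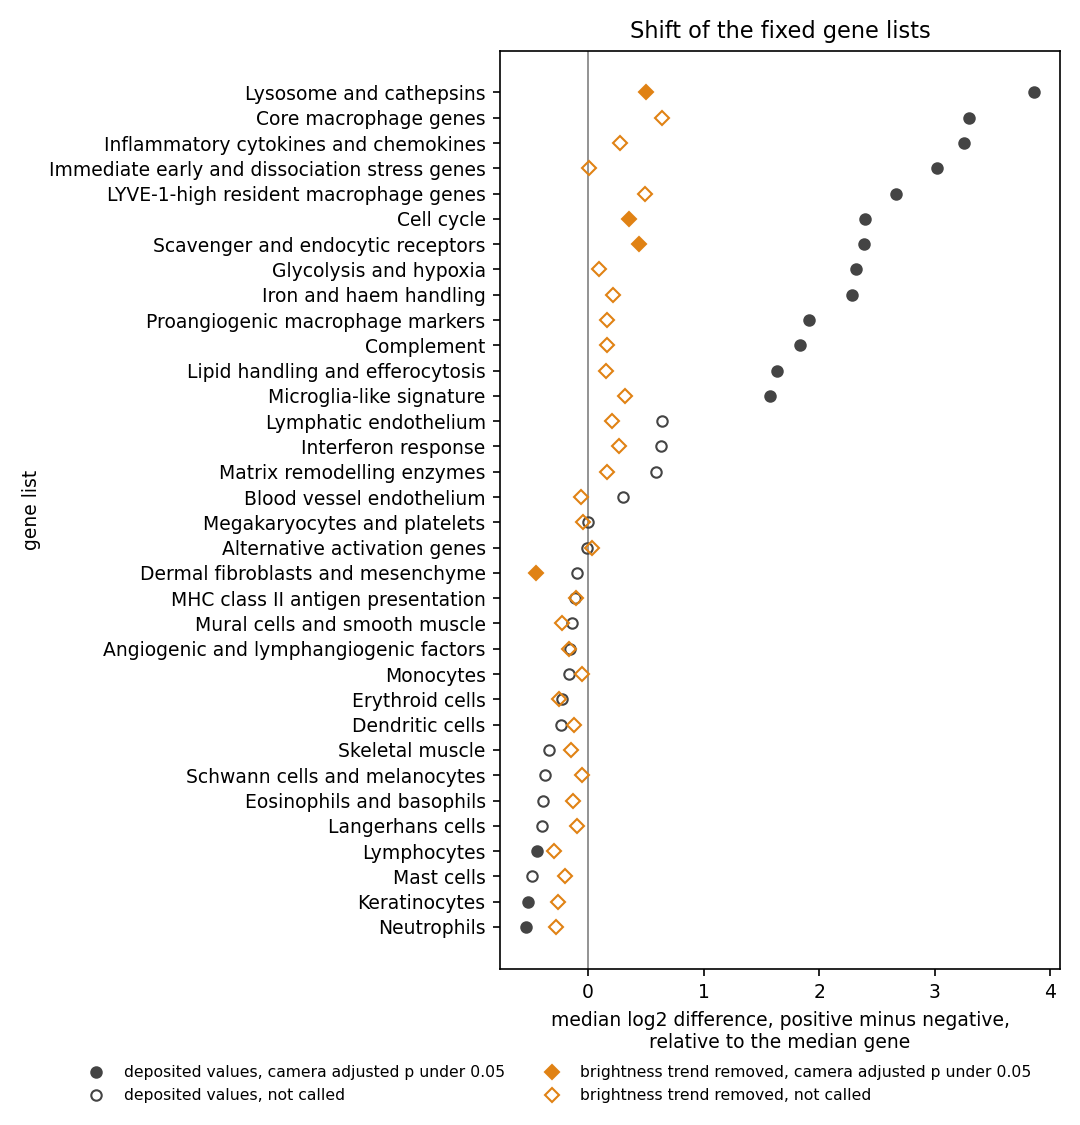
Median log2 difference of each of the 34 gene lists between LYVE-1 positive and LYVE-1 negative samples, relative to the median gene, on the deposited scale (grey circles) and with the brightness trend removed (orange diamonds); filled marks have a camera adjusted p under 0.05. The lysosome list moves from 3.86 to 0.50 and the core macrophage list from 3.29 to 0.64.

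In all, 13 of the 34 lists were called higher and 3 lower with the preset correlation. With an estimated correlation 0 were called, 0 had an unadjusted p under 0.05, and fry, a rotation test of one direction, called 13 higher and 16 lower. Adjusted over the list alone, the counts of members were the same for 29 of the lists. They changed for the other 5, to 3 lower in the inflammatory list, 2 lower in glycolysis, 0 lower in lymphatic endothelium, 5 lower in mural cells and 9 lower in monocytes.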

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

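The tests of this part were chosen after the results were seen. Probe sets with no gene in the annotation used here, which the comparison by gene left out, also differed between the groups. Of the 11989, 4271 were lower and 1116 higher in LYVE-1 positive samples (limma, adjusted p under 0.05), which was 44.9%.

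The widest pattern was that 14043 genes differed between the groups. Only 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05, and 1 of the 10 called as many genes, the real one, with 0 in the highest of the others (4 to 674 genes at an unadjusted p under 0.05). Weak signal on the LYVE-1 negative arrays may account for much of it, since the olfactory receptor family, sensory neuron genes that are dim on all arrays, had a median change of -0.998. Relative to the median gene the family stood at -0.489, and under quantile normalization its median change was -0.310. A difference between the macrophage populations stays open and cannot be told apart from weak signal, because the range of signal follows the groups. Without the LYVE-1 negative arrays 2 and 3, ribosomal protein genes had a median change of 0.143 and olfactory receptor genes of -0.617. The core macrophage, resident and lysosome lists then shifted by 2.08, 1.61 and 2.40 relative to the median gene. These values rest on 1 negative array, on which the 218 genes between 7 and 8 log2 units also lay lower, by a median of 1.35. With the brightness trend removed, camera with an estimated correlation called 0 lists. That cannot decide the question, since removal of the trend can take a true difference with it. The same setting also called 0 lists on the deposited scale and missed the list planted in the simulation (camera, adjusted p = 0.0858).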

How the results depend on the processing

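Cyclic loess and the fits without LYVE-1 negative arrays 2 and 3 were chosen after the data were examined; the rest was planned. The counts of genes higher and lower (5286 and 8757) moved with the scale and with the arrays left out, and the cause was not tested. Median centring gave 3972 lower, quantile normalization 1809 higher and 1244 lower, the 2-fold limit 4542 lower, and the filter on dim genes, which tests fewer genes, 1412 lower. Cyclic loess gave 2579 and 2474, leaving out the negative arrays 2 and 3 gave 3209 and 3809, and both together 0 and 0 (limma, smallest adjusted p 0.119, with 5068 genes at an unadjusted p under 0.05). An unmoderated test gave 3809 and 6093. Leaving out single arrays or numbers gave 2489 to 5454 higher and 739 to 9727 lower, with the fewest without replicate 2 (2489 and 739) and next without replicate 3 (3311 and 2435), while leaving out replicate 1, which also leaves 4 arrays, gave 5315 and 9197. Without positive array 2 or 3 the genes lower numbered 5691 and 5803. Lyve1 stayed higher at 3.33 to 4.95 in those fits, at 2.33 without the negative arrays 2 and 3, at 2.04 under quantile normalization, and lost its call at 0.41 with cyclic loess and 0.53 with both. Of the lists, 13 were higher and 3 lower. Quantile normalization gave 5 lower, the dim gene filter 8 higher, fry 16 lower, the estimated correlation 0 and 0, with or without the replicate block, cyclic loess 3 and 1, with the estimated correlation 0 and 0, the fit without the negative arrays 2 and 3 gave 7 lower, and both together 0 and 1 (fibroblasts, adjusted p = 0.0212). Leaving out arrays or numbers gave 12 to 14 higher and 3 to 6 lower. Several results reversed, and the cause was not tested apart from the first. The alternative activation list, with a shift of -0.0126 from the median gene and a median of -0.52, was uncalled and higher by camera and lower by fry, which compares it with no other genes. With cyclic loess Vegfc was at 0.0539, Vegfd 0.16, Tnf -0.63, Vegfb -0.70, C1qc -0.45, Cfp -0.0238, Col1a1 -1.81 and Col1a2 -1.70, and the immediate early list was lower by camera with its median shift at 0.0108 under both correlation settings. With both together Dnajc13 was at -0.31, Vegfc 0.0428, Tnf -0.77, Wnt7b 0.0203, H2-Ob 0.16, C1qc -0.17, Cx3cr1 -0.0424, Vegfb -0.47 and the glycolysis list -0.25. The labels do not say whether the replicate numbers pair the samples. Deviations from the group means correlated at -0.20, 0.07 and -0.12 for the numbers 1, 2 and 3, which shows no pairing but cannot exclude it. Within groups they reached -0.76 for the negative arrays 1 and 3 and -0.79 for the positive arrays 1 and 3. Deviations from a mean of 3 arrays sum to 0 for each gene, which by itself pulls correlations within a group below 0. Differences between the arrays of a group could still hide a pairing. With the replicate block 5146 genes were higher and 7722 lower, and 13 lists higher and 4 lower.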

Other observations

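The tests of this part were chosen after the values were seen, on marker lists fixed before the data were examined. Mast cell genes stood out on LYVE-1 negative array 1. Cpa3, mast cell carboxypeptidase, was at 7.24 log2 units there, against 4.92 and 4.13 on the negative arrays 2 and 3 and 4.17, 3.73 and 2.65 on the positive arrays. Hdc, which makes histamine, was at 7.51 on that array, the transcription factor Gata2 at 6.84, the chymase Cma1 at 6.39, the tryptase Tpsb2 at 5.90 and the receptor Kit at 5.42. Relative to the mean of the positive samples these were 3.73, 3.15, 2.65, 3.13, 2.14 and 1.60 log2 units higher. Hpgds went the other way, -3.25. Most of the other markers in the list were not highest on array 1 among the negative arrays. Rgs13 was 0.86 above the positive mean there, against 1.36 and 1.27 on the negative arrays 2 and 3. Gata1 was 0.73 above it, against 1.14 and 1.12.

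A collagen gene of dermal mesenchyme, Col1a1, was also bright on that array, at 8.10 against 7.36 on average on the positive arrays. It was at 5.90 and 5.26 on the negative arrays 2 and 3. Col5a2, another collagen gene, was at 4.11 on array 1, below its 4.65 and 4.47 on the negative arrays 2 and 3. With the brightness trend removed, Col1a1 was -1.81, Col1a2 -1.70 and Col6a1 -1.75 in positive against negative samples, each past the threshold in limma. On the deposited scale Col6a1 was called, at -0.82, and Col1a1 and Col1a2, which were not, stood at 0.94 and 0.06. Col5a2 was called on that scale, at -0.88, and not with the trend removed (-0.27, limma, adjusted p = 0.316).

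A candidate explanation for the mast cell genes is that sample 1 of the LYVE-1 negative group held mast cells, which the F4/80 selection should have reduced. The list's median there was 0.86 above the positive mean, higher than 100% of 10000 equally bright lists, and 8 of 17 markers were at least 2-fold higher where such lists had 1.09 on average. On the negative arrays 2 and 3 the list medians, 0.763 and 0.863, and the 7 and 7 markers at least 2-fold higher were much the same, but equally bright lists reached 6.23 and 7.51 such members there, and the list lay at percentiles 41.6 and 37.8. On array 1, 0% of equally bright lists had as many such members. This cannot decide on weak signal, since the list was picked because it stood out on that array. Small shares also arose elsewhere, 0.38% for keratinocytes on array 1 and 0.5% and 0.36% for neutrophils on the negative arrays 2 and 3. Fewer macrophages in sample 1 of the LYVE-1 negative group, which would raise every other cell type, stay open. The median core macrophage gene there lay 2.36 log2 units above the median olfactory receptor gene, against 4.77, 5.32 and 5.74 on the positive arrays. That distance was 0.87 and 0.70 on the negative arrays 2 and 3, and a narrower range of signal could also lower it. Of the other 15 lists, 5 passed the 95th percentile on array 1 (fibroblasts 99.39, keratinocytes 99.19, Langerhans cells 98.07, skeletal muscle 95.82, neutrophils 95.56). There 4 more lay between 92.78 and 94.09, and 14 of the 15 lay above the 50th, with dendritic cells the exception at 49.69. The finding rests on 1 array among 48 comparisons of 16 lists with 3 arrays, and 1 mast cell marker is also in another list.

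Prox1 was higher in LYVE-1 positive samples, and lymphatic endothelial cells, which carry LYVE-1, might have remained among them, although the F4/80 selection should have reduced them. The list of their markers lay at percentile 35.95 among equally bright lists. Single markers went apart among the 1000 genes nearest to each in brightness on the positive arrays, with Mmrn1 above 98.6% of them, Itga9 above 80.1% and Flt4 above 63.6%, and Mmrn1 passed with the trend removed (1.84). Such cells stay open. Weak signal on the negative arrays as the cause of the Prox1 difference stays open too. Its change lay above 91.3% of the 1000 genes nearest in brightness on the positive arrays, whose median was 1.40, and above 92.7% of those nearest over all 6 arrays. It passed with the trend removed (1.21) but not when the negative arrays 2 and 3 were also left out (0.72), a fit in which no gene passed.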
